A study of Homo sapiens with 36 samples.

How the data were processed

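The series holds 36 polyA RNA-seq libraries of MDA-MB-231 cells grown in RPMI-1640 with fetal bovine serum, per the labels' protocols. Drugs were added from stocks in DMSO, RNA was purified on columns with a DNase step, and polyA libraries were made by a service provider, per the labels' protocols. The authors deposited 3 tables of raw counts, 1 for each set of 12 libraries, with 54583 genes each. Per the submitters' processing notes, reads were handled with Trimmomatic, FastQC, HISAT2 and featureCounts on the build hg38. Versions, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told from those of their partners. The deposited counts are whole numbers, and no normalization by the authors was found in the values. Every column was joined to its sample by the treatment and replicate in its name and the table named in the sample's description, and 0 columns were left unused.

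Groups were taken from the sample labels alone. Within each table all 12 libraries entered 1 fit of 4 groups, with 3 libraries each and a shared estimate of the spread. Genes were kept by filterByExpr, library sizes were scaled with TMM factors, and edgeR 4.0.16 (limma 3.58.1, R 4.3.3) tested each contrast with the quasi-likelihood F-test on the counts. P-values were adjusted by Benjamini-Hochberg over the genes of a contrast, and an adjusted p under 0.05 counts as a call. Log2 fold changes are edgeR's, with a prior count of 0.125, and errors after them are standard errors. Levels are CPM, edgeR's counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries. For differences between sets, all 36 libraries entered 1 fit of 12 groups, and only differences of within-table contrasts were tested, since the tables are separate sets. Fold changes are relative to the other genes of a library, so a change of total RNA per cell is not seen. MG132 and carfilzomib were used at different doses, so their effects are set side by side and not at a matched dose.

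The contrasts, the 29 gene lists (638 symbols, 614 of them found in the tables), the rule for named genes and all alternatives except those said to be added were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. Each list count is given over all genes tested and adjusted over the list alone. The rule names the clock genes of both clock lists in any contrast, up to 10 highest and 10 lowest called genes of a contrast with a mean of at least 5 CPM and groups that do not overlap, up to 4 members of each list by p, and a short set of genes of the proteasome and its stress responses. POSTN outside the combination, CDKN2A, PSMD1, and the ribosomal RNA and liver genes were chosen after their values were seen. Of all tested genes, chance gives groups that do not overlap in 10% of cases with 3 against 3 libraries. Gene positions come from the RefSeq annotation of GRCh38.p14, matched by symbol, and the counting annotation may differ from it.

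The alternatives were relative log expression factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, a fit of only the groups compared and leaving out each library in turn. Added after the data were seen were fits without 2 libraries of the carfilzomib set at 8 h and without 4 libraries of the MG132 set. Depth was 34200000 to 39300000 counts per library in the MG132 set, 17800000 to 27700000 in the carfilzomib set at 8 h and 18900000 to 34000000 at 24 h. No 2 libraries of a group were identical, and every pair differed by more than counting noise. The method was tested on simulated data with 50 changed genes for each fold size. The counts were drawn from the means of the libraries labelled DMSO, the library sizes and the fitted spread of each gene within the labelled groups. For SHP1705 against DMSO in the MG132 set (16024 genes in the simulated step), 30 of 50 genes changed 1.25-fold, 41 changed 1.5-fold, 47 changed 2-fold and 49 changed 4-fold were recovered, and 8.74% of the 183 calls were false. In the same simulated comparison of the carfilzomib set, 0, 10, 33 and 48 were recovered at 8 h (15078 genes) and 19, 36, 43 and 49 at 24 h (15673 genes). The fitted coefficient of variation within groups was 0.172 at 8 h, against 0.0455 in the MG132 set and 0.0672 at 24 h. The recovery at 8 h therefore holds for the groups as labelled. For the simulated difference of SHP1705 effects between 24 h and 8 h (16949 genes), 2, 16, 36 and 47 were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.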

Results

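The data were gene-level read counts from polyA RNA-seq of MDA-MB-231 cells, a human triple-negative breast cancer line, after treatment with SHP1705, a proteasome inhibitor or both. SHP1705 stabilizes cryptochrome, the repressor protein of the circadian clock, and the title of the series names the CRY2 protein. MG132 and carfilzomib both block the proteasome, MG132 as a reversible peptide aldehyde and carfilzomib as an irreversible epoxyketone in clinical use. The 36 libraries formed 3 sets, with MG132 at 8 h, carfilzomib at 8 h and carfilzomib at 24 h. Each set held 4 groups of 3 libraries, namely DMSO, SHP1705 at 10 µM, the inhibitor (MG132 at 100 nM or carfilzomib at 10 nM) and both drugs together, called the combination here. Libraries of the MG132 set held 34200000 to 39300000 counts (median 36500000). Those of the carfilzomib set held 17800000 to 27700000 at 8 h (median 24100000) and 18900000 to 34000000 at 24 h (median 24600000). The design text speaks of 3 independent experiments without saying whether these are the replicates or the sets, so the p-values measure the spread between these libraries, which may be technical.

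The readout genes lie on GRCh38.p14 as follows. PER3, a period gene of the clock, spans chromosome 1 from 7784291 to 7845177, and ARNTL, which encodes the clock activator BMAL1, spans chromosome 11 from 13276652 to 13387266. The gene of the cryptochrome CRY1 covers 106991364 to 107093549 of chromosome 12. The inducible HSP70 genes HSPA1A (31815543 to 31817942) and HSPA1B (31827738 to 31830254) are neighbours on chromosome 6, and HSPA6, a strictly stress-induced HSP70, lies at 161524540 to 161526894 of chromosome 1. DNAJB1, an HSP40 co-chaperone, occupies 14514769 to 14560391 of chromosome 19, and PSMB5, the proteasome subunit that both inhibitors bind, occupies 23025851 to 23035220 of chromosome 14. AKR1B10, an aldo-keto reductase induced by the oxidative stress factor NRF2, lies on chromosome 7 (134527567 to 134541412). The aryl hydrocarbon receptor target CYP1B1 lies on chromosome 2 (38067509 to 38076151). POSTN, which encodes the matrix protein periostin, lies on chromosome 13 (37562585 to 37598768), and the cell cycle inhibitor gene CDKN2A on chromosome 9 (21967752 to 21995324). Counts were summed per gene, so all values are for whole annotated genes. HSPA1A and HSPA1B, HSPA6 and HSPA7, the metallothioneins and the ribosomal protein pseudogenes share sequence with close copies, and their individual values are uncertain.

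**Figure D1:**
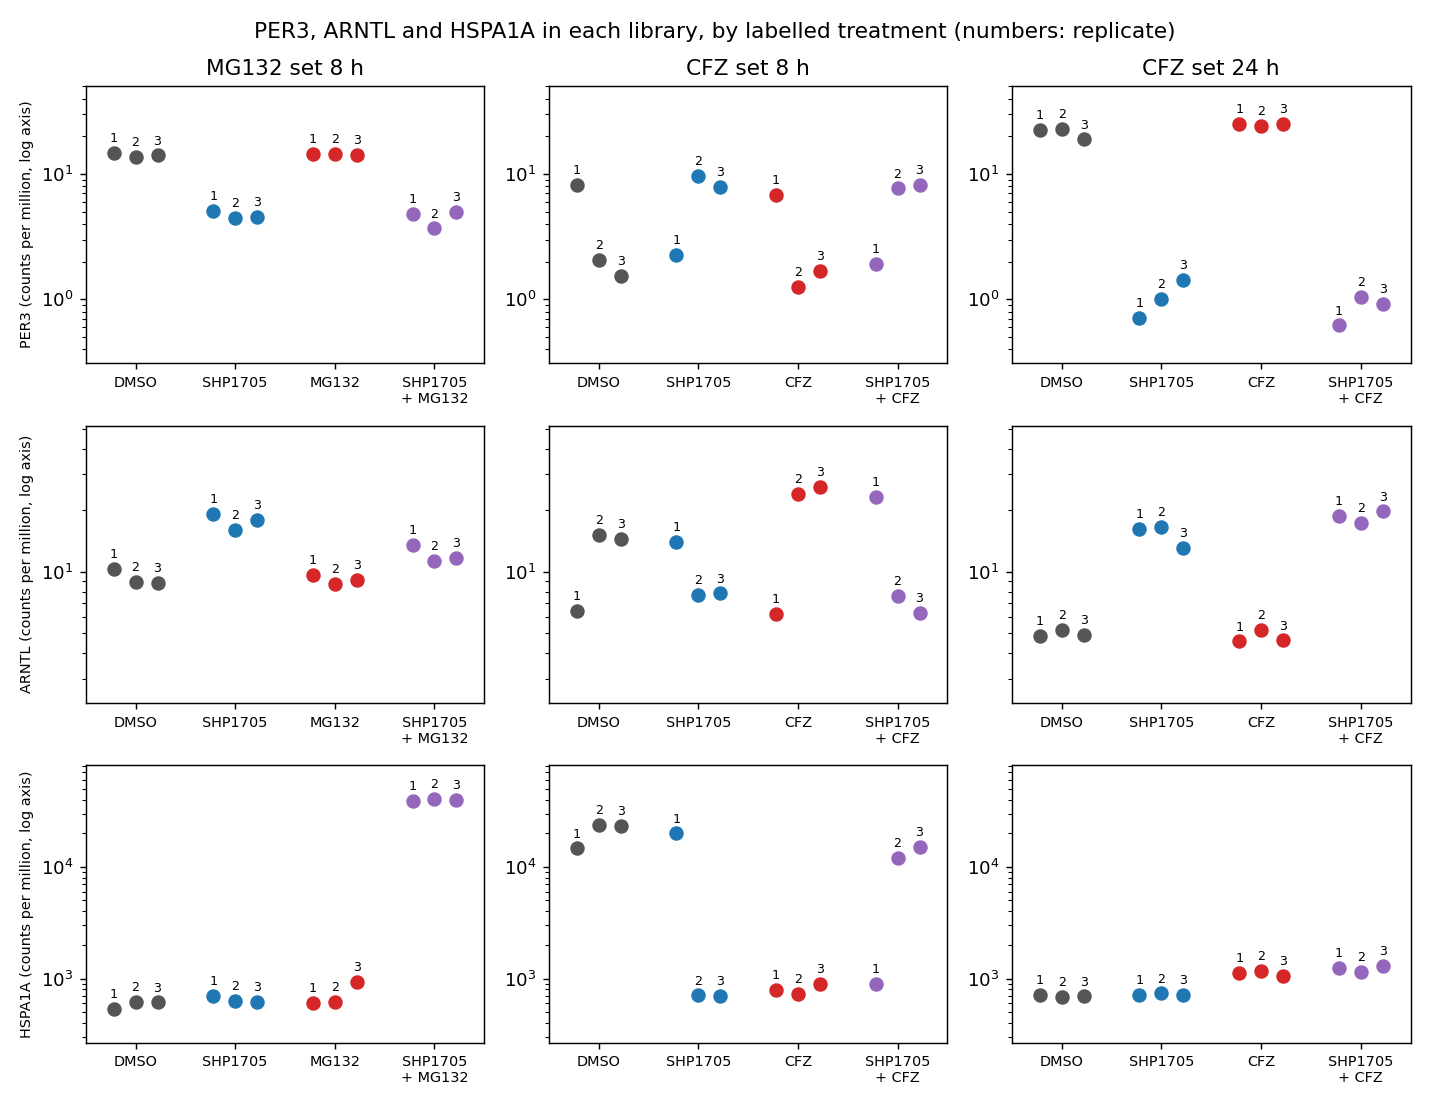
PER3, ARNTL and HSPA1A in each library in CPM (log axes), by set and labelled treatment, with 1 point per library marked with its replicate number. In the MG132 set and at 24 h, PER3 was lower in all libraries with SHP1705 than in those without it, whereas in the carfilzomib set at 8 h only 7 of the 36 pairs of a library labelled with SHP1705 and a library labelled without it had that order.

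The effect of SHP1705 alone after 8 h was read in the MG132 set. Genes that the BMAL1:CLOCK activator controls through E-box elements were lower after SHP1705, and genes under the ROR and REV-ERB nuclear receptors were higher. PER3 averaged 14.2 ± 0.439 CPM (counts scaled to the size of the library, SD, n = 3) in DMSO and 4.69 ± 0.335 with SHP1705, while ARNTL averaged 9.36 ± 0.806 and 17.7 ± 1.57. Of the 12 measured E-box clock genes, 10 fell and none rose (12 fell adjusted over the list alone), with a median log2 fold change of -1.32. Of the 6 measured ROR and REV-ERB clock genes, 3 rose (4 adjusted over the list alone). The falling genes included PER2 (log2 fold change -2.35 ± 0.27, SE), TEF (-2.76 ± 0.31) and DBP (-1.59 ± 0.35), the last 2 encoding transcription factors of clock output. NR1D1 (-1.79 ± 0.22) and NR1D2 (-1.33 ± 0.07), which encode the REV-ERB repressors, fell with them. CRY1 (-0.78 ± 0.06) and CRY2 (-0.50 ± 0.11), the genes of the proteins that SHP1705 acts on, also fell, CRY2 without a call when DMSO replicate 1 was left out (-0.38, adjusted p = 0.0535). Rising clock genes were ARNTL (0.92 ± 0.09), NFIL3 (0.45 ± 0.07), an opponent of DBP, and NPAS2 (0.34 ± 0.04), a CLOCK paralogue. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PER3 had an adjusted p of 3.29e-09 and ARNTL of 3.76e-06, each with all 3 libraries on one side of all 3 DMSO libraries. The camera calls of both clock lists held, with adjusted p = 8.7e-05 and adjusted p = 0.0042 with an estimated correlation.

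Outside the clock, further groups of genes changed after SHP1705 in the MG132 set. Of 11 aryl hydrocarbon receptor targets, which encode enzymes and regulators of xenobiotic metabolism, 5 rose (5 adjusted over the list alone), among them CYP1B1 (0.88 ± 0.05) and TIPARP (0.43 ± 0.05). Of 27 ribosome biogenesis and MYC target genes, 11 fell (13 adjusted over the list alone), among them the nucleolar protein gene NOP56 (-0.21 ± 0.03). These 2 calls held with an estimated correlation (adjusted p = 0.013 and adjusted p = 0.0043). Of 28 cytosolic ribosomal protein genes, 21 fell (27 adjusted over the list alone), such as RPS19 (-0.25 ± 0.04) and RPL27 (-0.29 ± 0.05), and this camera call was lost (adjusted p = 0.065 with an estimated correlation). Proteasome subunits showed 8 lower genes of 34 (14 adjusted over the list alone) with a median of -0.07 (adjusted p = 0.11 with an estimated correlation). Of 28 glycolysis and hypoxia genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with VEGFA, the angiogenic growth factor, at 0.38 ± 0.04 (adjusted p = 0.057 with an estimated correlation). Of 28 nuclear genes of oxidative phosphorylation, 8 fell (9 adjusted over the list alone), with a median of -0.09 (adjusted p = 0.08 with an estimated correlation). Of 13 mitochondrially encoded transcripts, 3 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.5 with an estimated correlation). Camera also called 14 replication-dependent histones (median -0.16, none called, 0 adjusted over the list alone) and 7 blood cell markers (median -0.83, none called, 0 adjusted over the list alone), and both calls were lost (adjusted p = 0.14 and adjusted p = 0.11 with an estimated correlation). PLAU, the urokinase gene, rose (0.34 ± 0.03). NEDD9, a focal adhesion scaffold, rose by 0.76 ± 0.08, and the metallothionein MT2A was at -0.45 ± 0.05.

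In all, 1249 of 16591 genes passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 after SHP1705 in the MG132 set (572 higher and 677 lower, against 648 and 605 with relative log expression factors and 738 and 685 by DESeq2, so no direction prevailed), of which 15 changed by 2-fold or more (3 higher, 12 lower). POSTN, chosen after its values were seen, was at 29.9 and 31.2 CPM in SHP1705 replicates 2 and 3 and at 0.284 in replicate 1, against 0.267 or less in DMSO. Leaving out the 4 libraries outside the combination with over 100 POSTN counts, which leaves SHP1705 and MG132 with 1 library each, gave 150 genes, 137 of them among the 1249 and with the same direction. In that fit DBP (-1.95, adjusted p = 0.129), CRY2 (-0.52, adjusted p = 0.147) and NOP56 (-0.21, adjusted p = 0.0529) were not called, and DESeq2 gave DBP no adjusted p. The count was 783, 619 and 825 without DMSO replicate 1, 2 or 3, and 780 and 689 without SHP1705 replicate 1 or 2, with fewer libraries in each fit.

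**Figure D2:**
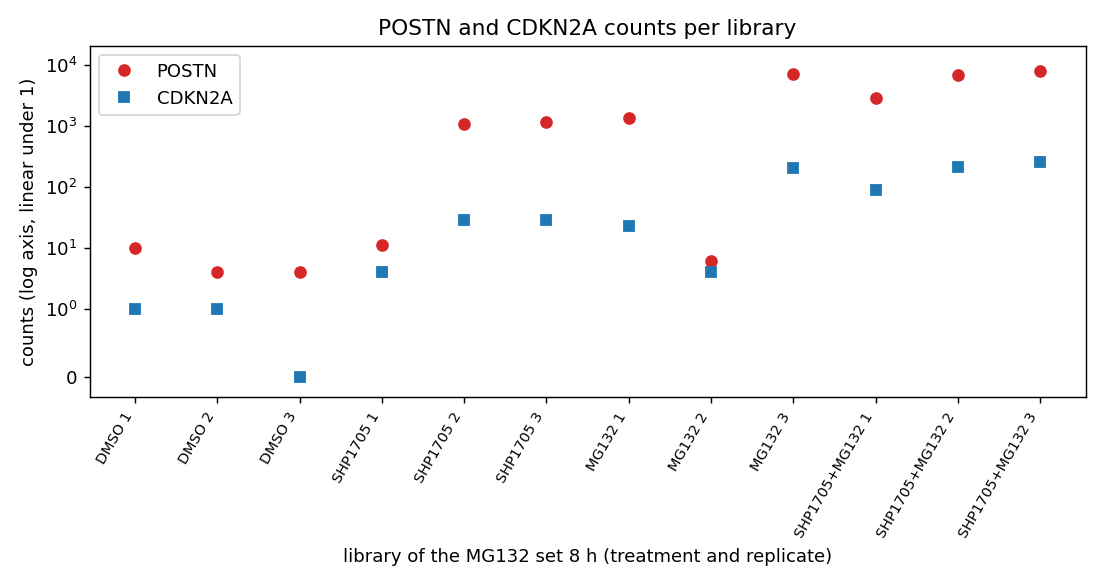
Counts of POSTN and CDKN2A in each library of the MG132 set, on an axis that is logarithmic above 1 and linear below. Both were high in the same 7 libraries, and POSTN reached 8040 counts in combination replicate 3.

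MG132 alone at 100 nM for 8 h was compared with DMSO to ask what the inhibitor does without SHP1705. Heat shock genes were close to the DMSO level, with a median log2 fold change of 0.00 over 25 genes and none called (0 adjusted over the list alone). HSPA1A averaged 716 ± 182 CPM (SD, n = 3) against 586.5 ± 46.1 in DMSO (log2 fold change 0.29 ± 0.10, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.377). It was at 608, 613 and 926 CPM in MG132 replicates 1, 2 and 3, and replicates 1 and 2 lay within the DMSO range of 533 to 615. Without the filter on low counts the same test called HSPA1A (adjusted p = 1.77e-40) despite this overlap. That fit also gave POSTN an adjusted p of 9.58e-227 in the combination against MG132, where the main fit made no call. Its p-values are therefore not taken as evidence of a rise. The 34 proteasome subunits had a median of -0.04 and none called (2 lower adjusted over the list alone), with PSMB5 at -0.06 ± 0.04. Clock genes were near their DMSO level as well, with PER3 at 14.4 ± 0.183 CPM. The edgeR quasi-likelihood test called 0 of 16591 genes, with 1574 at an unadjusted p under 0.05 where chance gives 830, and DESeq2 called 95. Among the lists, 28 cytosolic ribosomal protein genes had a median of -0.09 with 0 called (10 lower adjusted over the list alone), and their camera call at 1.1e-16 was lost (adjusted p = 0.31 with an estimated correlation). POSTN was at 35.6 and 183 CPM in MG132 replicates 1 and 3 and at 0.169 in replicate 2 (log2 fold change 8.72 ± 1.87, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.168), and it was called without the filter on low counts (8.72) and without MG132 replicate 2 (9.29, adjusted p = 0.00906). The fit without MG132 replicate 2 called 67 genes, the fit without MG132 replicate 1 called 1, and the fit of the MG132 and DMSO groups alone called 22.

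SHP1705 together with MG132 gave the widest response of the MG132 set, read first against DMSO. Chaperone genes of the heat shock response were higher, proteasome subunit genes were higher, stress response genes under ATF4 and NRF2 were higher, and mitotic genes were lower. HSPA1A averaged 39750 ± 843 CPM (SD, n = 3) against 586.5 ± 46.1 in DMSO, a log2 fold change of 6.08 ± 0.13. DNAJB1 averaged 3705 ± 22 against 256 ± 4.18 (3.86 ± 0.04), and HSPA6 154 ± 5.93 against 0.84 ± 0.0823 (7.51 ± 0.14). Of 25 heat shock genes, 24 rose (24 adjusted over the list alone) with a median of 1.86, including HSPH1 (2.73 ± 0.03), HSP90AA1 (2.49 ± 0.03) and the mitochondrial chaperonin HSPD1 (1.86 ± 0.03). Of 34 proteasome subunits, 33 rose (33 adjusted over the list alone) with a median of 0.79, led by the ATPase subunit PSMC4 (1.64 ± 0.04) and including PSMB5 (0.61 ± 0.04). Ubiquitin and autophagy genes rose in 19 of 25 cases and fell in 3 (19 and 3 adjusted over the list alone), with the stress-induced ZFAND2A at 3.94 ± 0.05, the autophagy receptor SQSTM1 at 1.84 ± 0.03 and GABARAPL1 at 3.77 ± 0.06.

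The stress pathways beyond heat shock moved with them in this combination. Of 26 ATF4 and integrated stress response genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone), among them CHAC1 (3.49 ± 0.17), which degrades glutathione, and CTH (3.23 ± 0.07), a cysteine synthesis enzyme. Of 21 endoplasmic reticulum chaperone genes, 19 rose (20 adjusted over the list alone), such as HSPA5 (2.01 ± 0.03) and HERPUD1 (2.34 ± 0.05). Of 25 NRF2 genes, 19 rose and 1 fell (19 and 2 adjusted over the list alone), such as HMOX1, the heme oxygenase (2.83 ± 0.06), and the cystine transporter SLC7A11 (2.85 ± 0.05). NF-kB and cytokine genes rose in 16 of 21 cases and fell in 2 (16 and 2 adjusted over the list alone), with BIRC3 at 2.12 ± 0.05. All 26 G2 and mitosis genes fell (26 adjusted over the list alone), including the kinesin KIF20A (-1.87 ± 0.04), the kinase PLK1 (-1.71 ± 0.04) and CDC20 (-1.46 ± 0.03). The camera calls of the heat shock, proteasome, ubiquitin, ATF4, endoplasmic reticulum, NRF2, NF-kB and mitosis lists held with an estimated correlation (adjusted p = 0.0024 at the highest, camera). DNA replication genes fell in 23 of 29 cases and rose in 2 (23 and 2 adjusted over the list alone), and that call was lost (adjusted p = 0.055 with an estimated correlation). PLAU fell (-1.83 ± 0.03), as did the transcription regulator TRERF1 (-2.84 ± 0.06) and the phosphodiesterase PDE7B (-2.81 ± 0.10), while MYC rose (0.73 ± 0.04).

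Clock genes in the combination of the MG132 set moved in part as with SHP1705 alone. PER3 (-1.66 ± 0.10), TEF (-2.65 ± 0.32), DBP (-2.06 ± 0.38) and NR1D1 (-1.82 ± 0.23) fell against DMSO, and ARNTL rose (0.37 ± 0.09). CRY2 rose (1.21 ± 0.10), and NPAS2 fell (-0.79 ± 0.04). Of the 12 E-box genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone), which camera did not call (adjusted p = 0.091). POSTN was at 84.1, 187 and 205 CPM in the 3 combination libraries, with a log2 fold change of 10.15 ± 1.70. CDH2, the N-cadherin gene, was at 3.37 ± 0.63. It had 191 to 521 counts in the combination, 472 in MG132 replicate 3 and 36 to 61 in DMSO. CDKN2A had 90 to 252 counts in the combination libraries and 1 or fewer in DMSO. RNA from other cells, weighed below, thus coincides with the drugs in this contrast. The fold changes of POSTN and CDH2 are therefore not read as drug effects, and the count that follows may include such genes. In all, 9763 of 16591 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (4838 higher, 4925 lower), 1810 of them by 2-fold or more (976 higher, 834 lower). In this test DNAJB1 had an adjusted p of 1.59e-22, HSPA6 of 7.55e-19, KIF20A of 2.1e-18, HSPA1A of 3.27e-18 and PSMC4 of 4.43e-18, with all 3 combination libraries beyond all 3 DMSO libraries. The fold changes are relative to the rest of the transcriptome, since HSPA1B alone took 4.47% to 4.61% of all counts in the combination libraries, where TUBB led the other libraries at about 1.5%.

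**Figure D3:**
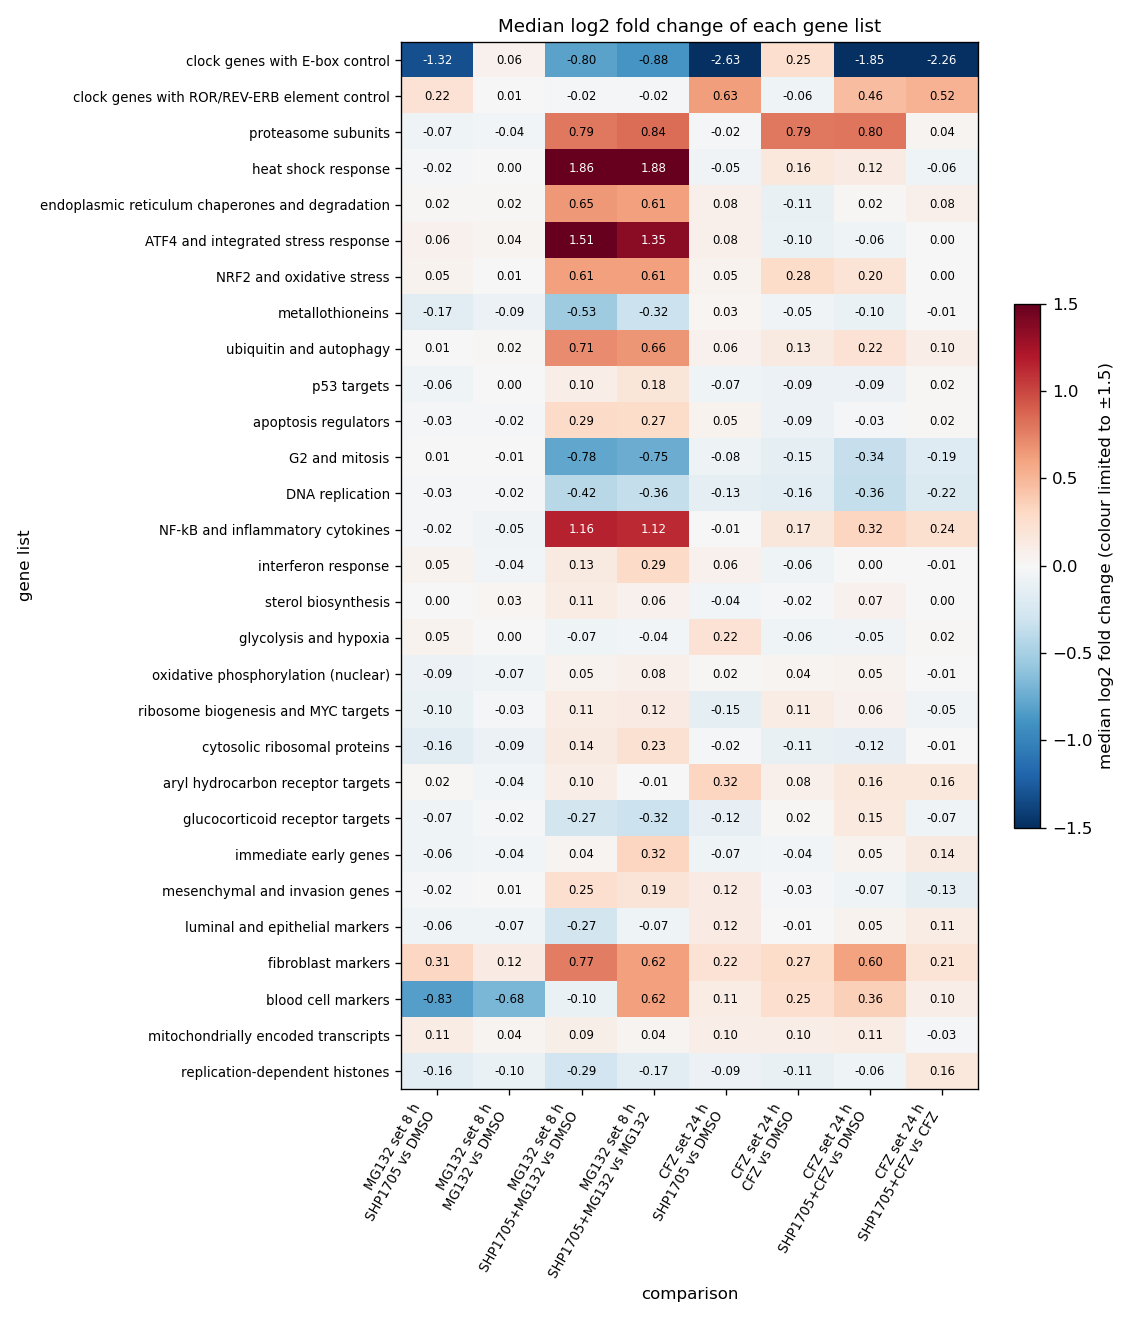
Median log2 fold change of each gene list (vertical axis) in the comparisons of the MG132 set and of the carfilzomib set at 24 h (horizontal axis), with colour and printed numbers giving the median. The heat shock list stood at 1.86 in the combination of the MG132 set against DMSO and at 0.16 with carfilzomib at 24 h.

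What SHP1705 added to MG132 was read between the combination and MG132 alone, which shares no library with SHP1705 against DMSO. The same stress groups were higher and the mitotic group lower, since MG132 alone lay near DMSO. With 0 genes called for MG132 alone, a dose of MG132 that differed between the groups cannot be told from an addition by SHP1705. HSPA6 (log2 fold change 6.98 ± 0.13), HSPA1A (5.80 ± 0.13), DNAJB1 (3.82 ± 0.04) and BAG3 (2.95 ± 0.04), a co-chaperone of HSP70, rose. All 25 heat shock genes rose (25 adjusted over the list alone, median 1.88), as did 33 of 34 proteasome subunits (33 adjusted over the list alone, median 0.84), and all 26 G2 and mitosis genes fell (26 adjusted over the list alone, median -0.75). PER3 (-1.68 ± 0.10), TEF (-2.93 ± 0.32) and NR1D2 (-0.69 ± 0.07) fell, ARNTL rose (0.40 ± 0.09), and SLCO4A1, a transporter gene, fell (-2.39 ± 0.12). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 9487 genes (4684 higher, 4803 lower), of which 1513 changed by 2-fold or more. POSTN was at 84.1 to 205 CPM in the combination and at 0.169 to 183 with MG132 alone.

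The interaction in the MG132 set asks whether the combination departs from the sum of both single effects on the log2 scale. It did for the heat shock genes, all 25 of which had a positive term (25 adjusted over the list alone, median 1.89), and for all 34 proteasome subunits (34 adjusted over the list alone, median 0.95). HSPA6 had a term of 6.72 ± 0.44, HSPA1A of 5.65 ± 0.16, DNAJB1 of 3.78 ± 0.05 and HMOX1 of 2.52 ± 0.09. All 26 G2 and mitosis genes had a negative term (26 adjusted over the list alone, median -0.76), with KIF20A at -1.86 ± 0.05 and PLK1 at -1.61 ± 0.05. These 3 camera calls held (adjusted p = 1.6e-05, adjusted p = 0.0011 and adjusted p = 0.0031 with an estimated correlation). Among clock genes, CRY2 (1.45 ± 0.14), PER2 (1.29 ± 0.36), NR1D2 (0.64 ± 0.10) and CRY1 (0.39 ± 0.08) had positive terms, and NPAS2 (-1.13 ± 0.06), NFIL3 (-0.62 ± 0.10) and ARNTL (-0.51 ± 0.12) negative ones. All 28 cytosolic ribosomal protein genes had a positive term (28 adjusted over the list alone, median 0.38), a call that was lost (adjusted p = 0.25 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 8108 genes passed (4100 positive, 4008 negative). MG132 alone had called 0 genes, so a dose of MG132 that differed between the groups would give such terms as well. POSTN stood at 29.9 to 205 CPM in 7 libraries of the 3 drug groups, and without the 4 of them outside the combination, which leaves SHP1705 and MG132 with 1 library each, 5982 genes passed, 5671 of them shared and in the same direction.

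SHP1705 alone for 24 h was read in the later carfilzomib set. The clock genes again led the changes, with PER3 at 21.4 ± 2.25 CPM (SD, n = 3) in DMSO and 1.05 ± 0.363 with SHP1705, and CRY1 at 35.6 ± 1.82 and 5.85 ± 0.486. All 12 measured E-box clock genes fell (12 adjusted over the list alone) with a median log2 fold change of -2.63. PER2 (-5.18 ± 0.41), PER3 (-4.34 ± 0.17), TEF (-3.56 ± 0.20), DBP (-3.30 ± 0.28), PER1 (-2.65 ± 0.21), CRY1 (-2.61 ± 0.09) and CRY2 (-1.79 ± 0.14) were among them. Of the 6 ROR and REV-ERB clock genes, 3 rose (3 adjusted over the list alone), ARNTL (1.60 ± 0.12), NFIL3 (0.70 ± 0.11) and NPAS2 (0.55 ± 0.06). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PER3 had an adjusted p of 3.43e-14, CRY1 of 1.07e-14 and ARNTL of 7.56e-09, with all 3 libraries beyond all 3 DMSO libraries. Both camera calls held (adjusted p = 8.5e-08 and adjusted p = 0.00088 with an estimated correlation).

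Metabolic and growth genes accompanied the clock genes at 24 h. Of 27 glycolysis and hypoxia genes, 15 rose (22 adjusted over the list alone), among them the pH regulator CA9 (0.81 ± 0.10), the glycolytic regulator PFKFB4 (0.55 ± 0.06), the collagen hydroxylase P4HA1 (0.40 ± 0.05) and PGK1 (0.29 ± 0.04). Of 27 ribosome biogenesis and MYC target genes, 10 fell (15 adjusted over the list alone), such as BOP1 (-0.54 ± 0.06), RRP9 (-0.54 ± 0.07) and NCL, the nucleolin gene (-0.26 ± 0.04). Of 29 DNA replication genes, 6 fell (9 adjusted over the list alone), including E2F1 (-0.30 ± 0.06) and SLBP (-0.36 ± 0.06), the histone mRNA binding protein. Aryl hydrocarbon receptor targets rose in 5 of 11 cases (6 adjusted over the list alone), with CYP1A1 at 0.93 ± 0.15 and CYP1B1 at 0.47 ± 0.05. Endoplasmic reticulum chaperone genes rose in 5 of 21 cases (6 adjusted over the list alone), with HSPA5 at 0.24 ± 0.04. Mesenchymal and invasion genes rose in 7 of 23 cases and fell in 1 (10 and 1 adjusted over the list alone), with PLAU at 0.76 ± 0.04 and TGFBI at 0.42 ± 0.05. These 6 calls held with an estimated correlation (adjusted p = 0.035 at the highest, camera). None of 34 proteasome subunits was called (0 adjusted over the list alone, median -0.02). GDF15, a stress cytokine, rose (0.96 ± 0.12), and the kinase gene CAMKK1 fell (-2.06 ± 0.16). In all, 722 of 16183 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (316 higher, 406 lower), 39 by 2-fold or more. The count was 419 and 427 without DMSO replicate 1 or 2, 469 and 439 without SHP1705 replicate 2 or 3, and 1171 in the fit of SHP1705 and DMSO alone.

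Carfilzomib alone for 24 h was compared with DMSO for the effect of the irreversible inhibitor. Proteasome subunit genes were higher, NRF2 targets and part of the heat shock genes were higher, and the clock genes moved little. AKR1B10 averaged 22.5 ± 1.24 CPM (SD, n = 3) against 1.06 ± 0.133 in DMSO (log2 fold change 4.41 ± 0.13), and PSMC4 473 ± 36 against 192 ± 6.63 (1.31 ± 0.05). Of 34 proteasome subunits, 33 rose (33 adjusted over the list alone) with a median of 0.79, including PSMB2 (1.03 ± 0.04), PSMD13 (1.14 ± 0.05) and PSMB5 (0.63 ± 0.05). Of 25 NRF2 genes, 13 rose and 4 fell (13 and 5 adjusted over the list alone), with the biliverdin reductase BLVRB at 1.18 ± 0.05 and ME1, the malic enzyme, at 1.16 ± 0.09. Of 24 heat shock genes, 10 rose and 3 fell (12 and 4 adjusted over the list alone), with HSPA6 at 2.57 ± 0.17, the small heat shock protein HSPB8 at 1.67 ± 0.10 and HSPA1A at 0.67 ± 0.05. Ubiquitin and autophagy genes rose in 12 of 25 cases and fell in 1 (12 and 2 adjusted over the list alone), with GABARAPL1 at 1.56 ± 0.08 and the segregase VCP at 0.81 ± 0.04. These 4 calls held with an estimated correlation (adjusted p = 0.024 at the highest, camera). G2 and mitosis genes fell in 11 of 26 cases (15 adjusted over the list alone), such as UBE2C (-0.36 ± 0.05), and that call was lost (adjusted p = 0.079 with an estimated correlation). The ganglioside synthase B4GALNT1 (2.86 ± 0.13) and GLA, the lysosomal galactosidase (1.75 ± 0.07), rose, and SLCO4A1 (-1.15 ± 0.10) and the oxidase NOX5 (-1.14 ± 0.13) fell. Of the clock genes, NR1D2 rose (0.45 ± 0.07) and NPAS2 fell (-0.35 ± 0.06). With Benjamini-Hochberg adjustment, edgeR's quasi-likelihood test called 3472 genes (1631 higher, 1841 lower), with an adjusted p of 3.25e-16 for AKR1B10 and 2.6e-14 for PSMC4, both higher in all 3 carfilzomib libraries than in all 3 DMSO libraries.

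In the combination at 24 h, E-box clock genes were lower than in DMSO, proteasome subunit genes were higher and cell cycle genes were lower. PER3 averaged 0.866 ± 0.223 CPM (SD, n = 3) against 21.4 ± 2.25 in DMSO (log2 fold change -4.63 ± 0.18), and AKR1B10 26.4 ± 0.85 against 1.06 ± 0.133 (4.64 ± 0.13). Of 12 E-box clock genes, 11 fell (12 adjusted over the list alone), and of 34 proteasome subunits 33 rose (33 adjusted over the list alone, median 0.80). Of 26 G2 and mitosis genes, 25 fell (25 adjusted over the list alone), including CDK1 (-0.68 ± 0.07), MKI67 (-0.53 ± 0.05) and UBE2C (-0.74 ± 0.05). Of 29 DNA replication genes, 23 fell (26 lower and 1 higher adjusted over the list alone), including E2F1 (-0.61 ± 0.06) and the helicase subunit MCM4 (-0.47 ± 0.05). These 4 calls held with an estimated correlation (adjusted p = 0.0012 at the highest, camera). HSPA6 (3.24 ± 0.17) and HSPA1A (0.81 ± 0.05) rose, while HSPA8, the constitutive HSP70, fell (-1.03 ± 0.05), and so did the polyubiquitin gene UBB (from 1589 ± 59.1 to 797 ± 60.2 CPM). IL6, the inflammatory cytokine, rose (1.67 ± 0.18), as did ARNTL (1.89 ± 0.12). In all, 4424 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (2109 higher, 2315 lower).

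Adding SHP1705 to carfilzomib for 24 h was read between the combination and carfilzomib alone. E-box clock genes were lower, cell cycle genes were lower and the urokinase gene PLAU was higher. PER3 (log2 fold change -4.84 ± 0.17), NR1D1 (-2.72 ± 0.21) and CRY1 (from 35.45 ± 2.39 to 12.5 ± 0.603 CPM) fell, and ARNTL rose (1.94 ± 0.12). Of 12 E-box clock genes, 11 fell (12 adjusted over the list alone, median -2.26). PLAU averaged 301.5 ± 6.6 CPM (SD, n = 3) against 146 ± 5.18 (1.05 ± 0.04), and the epithelial factor ELF3 (1.07 ± 0.11) and PLAT (0.88 ± 0.05), the tissue plasminogen activator, rose as well. Of 29 DNA replication genes, 14 fell (22 adjusted over the list alone), such as RRM2 (-0.34 ± 0.05) and POLA1 (-0.42 ± 0.06), and of 26 G2 and mitosis genes 13 fell (17 adjusted over the list alone), such as CDK1 (-0.53 ± 0.07) and MKI67 (-0.39 ± 0.05). These 3 calls held with an estimated correlation (adjusted p = 0.0023 at the highest, camera). NF-kB and cytokine genes rose in 8 of 22 cases (9 adjusted over the list alone), with IL6 at 0.81 ± 0.17 and ICAM1 at 0.38 ± 0.08, a call that was lost (adjusted p = 0.16 with an estimated correlation). Proteasome subunits rose in 5 of 34 cases and fell in 2 (6 and 3 adjusted over the list alone, median 0.04). HSPA8 (-0.74 ± 0.05) and UBB (-0.52 ± 0.06) fell. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1460 genes (705 higher, 755 lower). That count was 877 and 869 without combination replicate 2 or 3, and 913 in the fit of the combination and carfilzomib groups alone, 903 of them shared.

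The interaction at 24 h tested whether the combination departs from the sum of both drugs. HSPA8 had a negative term (-0.60 ± 0.07), as did the polyubiquitin gene UBB (-0.55 ± 0.08) and DNAJA1 (-0.37 ± 0.06), an HSP40 partner of HSPA8. Among clock genes, CRY1 had a positive term (1.10 ± 0.13) and NR1D2 a negative one (-0.87 ± 0.11). LDHA (-0.39 ± 0.06), the lactate dehydrogenase gene, NDRG1 (-0.37 ± 0.06) and P4HA1 (-0.44 ± 0.07) were among 6 of 27 glycolysis and hypoxia genes with a negative term (11 adjusted over the list alone), a camera call that held (adjusted p = 0.03 with an estimated correlation). None of 34 proteasome subunits was called (5 positive adjusted over the list alone, median 0.06). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 78 genes passed (34 positive, 44 negative), CRY1 and HSPA8 with an adjusted p of 0.000104 each. Without DMSO replicate 1, 2 or 3 the count was 21, 24 and 27, without SHP1705 replicate 1, 2 or 3 it was 170, 20 and 29, without carfilzomib replicate 2 it was 477, and without combination replicate 1, 2 or 3 it was 20, 23 and 25. DESeq2 called 360 genes (193 positive, 167 negative), 63 of them shared, and gave CRY1 no adjusted p (1.10), and edgeR without a filter on low counts called 364 (208 positive, 156 negative).

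In the carfilzomib set at 8 h, the readouts of both drugs went against the labels of part of the libraries. HSPA1A stood at 14600, 23600 and 23200 CPM in the libraries labelled DMSO replicates 1, 2 and 3, and at 792, 726 and 896 in those labelled carfilzomib. It was at 19900, 705 and 693 in the libraries labelled SHP1705 and at 892, 12000 and 15100 in those labelled with both drugs. The DMSO libraries of the other sets held 533 to 715 CPM. PER3 was at 8.19, 2.06 and 1.55 in the libraries labelled DMSO, 2.25, 9.62 and 7.91 in those labelled SHP1705, 6.78, 1.26 and 1.69 in those labelled carfilzomib and 1.92, 7.69 and 8.20 in those labelled with both. The library labelled SHP1705 replicate 1 also held 15700 CPM of the ribosomal RNA pseudogene RNA18SP4, against 499 to 1630 in the other 11. Directions below are those of the labels and are given for the libraries labelled so.

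The libraries labelled carfilzomib at 8 h had lower stress genes than the libraries labelled DMSO, the opposite order to that at 24 h. HSPA6 (log2 fold change -5.33 ± 1.52), HSPA1A (-4.67 ± 1.28), AKR1B10 (-4.13 ± 1.12) and DNAJB1 (-3.25 ± 0.86) were lower, and SLCO4A1 (3.62 ± 0.92), PDE7B (2.95 ± 0.74) and PLAU (2.44 ± 0.60) higher. Of 24 heat shock genes, 21 were lower (24 adjusted over the list alone, median -1.48), and of 34 proteasome subunits 32 were lower (32 adjusted over the list alone, median -0.82), while 11 of 26 G2 and mitosis genes were higher (19 adjusted over the list alone). These 3 camera calls were lost (adjusted p = 0.57 with an estimated correlation for each). Of 13 luminal and epithelial markers, 6 were higher and 1 lower (8 and 1 adjusted over the list alone, median 0.48), and 13 mitochondrially encoded transcripts had a median of -0.33 with none called (0 adjusted over the list alone), and these camera calls were lost as well (adjusted p = 0.57 and adjusted p = 0.62 with an estimated correlation). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 3587 of 15577 genes (1824 higher, 1763 lower), all with an adjusted p of 0.04 or more, HSPA1A among them with all 3 libraries labelled carfilzomib below all 3 labelled DMSO. It called 0 without the library labelled DMSO replicate 2 or 3 or without any one of the libraries labelled carfilzomib, and 6719 in the fit of those 2 groups alone.

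For the libraries labelled SHP1705 or with both drugs at 8 h, no gene passed. Between the libraries labelled SHP1705 and DMSO, the edgeR quasi-likelihood test called 0 genes (2244 at an unadjusted p under 0.05, DESeq2 0), and PER3 averaged 6.6 ± 3.86 and 3.93 ± 3.7 CPM (SD, n = 3). The libraries labelled with both drugs gave 0 genes against those labelled DMSO (1454 at an unadjusted p under 0.05, DESeq2 1) and 0 against those labelled carfilzomib (898 at an unadjusted p under 0.05, DESeq2 1), with HSPA1A at 9321 ± 7460, 20470 ± 5120 and 804.5 ± 85.6. For the interaction, edgeR called 0 (3951 at an unadjusted p under 0.05, DESeq2 315). The heat shock list had medians of -0.82, -0.69, 0.78 and 1.52 in these 4 comparisons with 0 of 24 genes called (0, 0, 0 and 23 adjusted over the list alone), and its camera calls were lost (adjusted p = 0.45, adjusted p = 0.72, adjusted p = 0.6 and adjusted p = 0.51 with an estimated correlation). Without the library labelled SHP1705 replicate 1, the SHP1705 comparison gave 3662 genes and the interaction 5093, and without the library labelled with both drugs replicate 1 the interaction gave 2837. Without the library labelled carfilzomib replicate 3, the libraries labelled with both drugs gave 2 genes against carfilzomib.

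Differences between the sets were tested in 1 fit of all 36 libraries, and each of them that uses the carfilzomib set at 8 h depends on its labels. The carfilzomib effect at 24 h minus that of the labels at 8 h was positive for AKR1B10 (8.55 ± 0.97), HSPA6 (7.90 ± 1.42) and HSPA1A (5.34 ± 1.05), and for 33 of 34 proteasome subunits (33 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). It was negative for SLCO4A1 (-4.78 ± 0.78) and PLAU (-2.66 ± 0.52), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6965 of 17389 genes (3482 positive, 3483 negative). The effect of both drugs at 24 h minus that of the labels at 8 h gave 3542 genes (1690 positive, 1852 negative), with PER3 at -5.28 ± 0.76, DBP at -4.95 ± 0.75 and AKR1B10 at 5.53 ± 0.85. It gave 2231 without the library labelled DMSO replicate 3 at 8 h and 2126 without that labelled with both drugs replicate 1. The carfilzomib labels at 8 h minus MG132 gave 5187 genes (2568 positive, 2619 negative), with HSPA1A at -4.96 ± 1.04 and PSMC4 at -1.60 ± 0.34, and 3354 without the library labelled DMSO replicate 3. In that contrast 24 of 25 heat shock genes were negative (24 adjusted over the list alone, adjusted p = 0.3 with an estimated correlation).

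The SHP1705 effect at 24 h minus that of the labels at 8 h was negative for PER3 (-5.17 ± 0.75), DBP (-4.87 ± 0.71), PER1 (-2.76 ± 0.53) and CRY1 (-2.70 ± 0.37). Of 13 E-box clock genes, 9 were negative (11 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation), and of 28 glycolysis and hypoxia genes 12 were positive (18 positive and 1 negative adjusted over the list alone, adjusted p = 0.00011 with an estimated correlation), such as PGK1 (0.62 ± 0.11). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 512 genes (225 positive, 287 negative). The count was 1757, 82 and 82 without the libraries labelled DMSO replicate 1, 2 or 3 at 8 h, 4825, 76 and 89 without those labelled SHP1705 at 8 h, 162, 183 and 263 without those of DMSO at 24 h, and 311, 193 and 212 without those of SHP1705 at 24 h. In the fit of only those groups it was 4, with PER3 (-5.14, adjusted p = 0.0582), DBP (-4.86, adjusted p = 0.0582), PER1 (-2.75, adjusted p = 0.0582) and PGK1 (0.61, adjusted p = 0.241) no longer called, and by DESeq2 1252. The SHP1705 effect of the labels in the carfilzomib set at 8 h minus that in the MG132 set at the same time gave 0 genes by edgeR (3240 at an unadjusted p under 0.05, DESeq2 368), and 4629, 729, 1 and 1 without the libraries labelled SHP1705 replicate 1, DMSO replicate 1 and DMSO replicate 2 of that set or SHP1705 replicate 2 of the MG132 set.

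The SHP1705 effects were also compared across genes, between comparisons that share no library. These correlations run across genes, which are not independent replicates, so no p is given. Between SHP1705 against DMSO in the MG132 set and at 24 h, Pearson's r was 0.17 and Spearman's rho 0.23 over 15613 genes, and 211 genes were called in both, 208 of them with the same sign, where independent lists would share 58. PER3, CRY1 and ARNTL were among the clock genes called in both, and without the clock genes r was 0.13. At 24 h, SHP1705 alone and SHP1705 on top of carfilzomib gave r = 0.18 and rho = 0.20, with 280 genes called in both, 276 with the same sign, where independent lists would share 65. In the MG132 set the corresponding pair gave r = 0.02 and rho = -0.04, with 973 genes called in both and 420 with the same sign, where independent lists would share 714. Over genes with a mean of at least 5 CPM, r was 0.41 for SHP1705 between the MG132 set and 24 h, 0.50 for SHP1705 alone and on top of carfilzomib at 24 h and -0.01 for the pair of the MG132 set. In the carfilzomib set at 8 h that pair gave r = -0.59 and rho = -0.66 across the libraries as labelled, and r = -0.81 over genes with a mean of at least 5 CPM. The SHP1705 effect of those labels gave r = 0.05 with the MG132 set and r = 0.03 with 24 h. Leaving out 1 library at a time gave r of 0.11 to 0.16 between the MG132 set and 24 h. For SHP1705 alone and on top of the inhibitor, it gave -0.01 to 0.09 in the MG132 set and 0.14 to 0.19 at 24 h. The labels at 8 h gave -0.70 to -0.45 for that pair, 0.03 to 0.09 with the MG132 set and 0.01 to 0.04 with 24 h.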

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

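The tests in this part, with their bounds, and the splits of the samples were chosen after the values were seen. Each of the 6 results below was picked out by a test of a difference between the effects of 2 groups. In the MG132 set, the SHP1705 effect differed between cells with and without MG132 for 8108 genes, with HSPA1A and DNAJB1 among the positive terms and KIF20A among the negative ones. At 24 h, it differed between cells with and without carfilzomib for 78 genes, among them HSPA8 and UBB. Between 24 h and the labels at 8 h, the carfilzomib effect differed for 6965 genes (AKR1B10 and HSPA1A higher at 24 h), the effect of both drugs for 3542 (PER3 lower at 24 h) and the SHP1705 effect for 512 (CRY1 lower at 24 h). Between the carfilzomib labels at 8 h and MG132, 5187 genes differed, HSPA1A among them.

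In the carfilzomib set at 8 h, readouts of both drugs went against the labels, and 3 explanations were weighed. PER3 was lower in the library labelled SHP1705 in 7 of 36 pairs, against 36 and 36 of 36 in the MG132 set and at 24 h, a count that restates the pattern, so a mislabelling of libraries stays open. PSMD1, a proteasome subunit gene, was higher in the library labelled with the inhibitor in 7 of 36 pairs (29 in the MG132 set, 36 at 24 h), HSPA1A in 13 (27 and 36) and ARNTL in the one labelled with SHP1705 in 13 (36 and 36), and the widest gaps in PER3 (3.01-fold) and HSPA1A (13.4-fold) each part 6 libraries from 6, with 3 in each of the 4 crossings. HSPA1A in the lowest library labelled DMSO was 20.4 times the highest DMSO library of the other sets, past the bound of 2-fold set for an uneven response. That value restates the pattern too and compares levels between sets. On its own it cannot exclude an uneven response of correctly labelled libraries, such as stress in the DMSO cultures. Yet PER3 was low with ARNTL high in libraries labelled without SHP1705. PER3 was 2.06 and 1.55 and ARNTL 15.2 and 14.5 in DMSO replicates 2 and 3. In carfilzomib replicates 2 and 3, PER3 was 1.26 and 1.69 and ARNTL 24 and 25.9, with HSPA1A at 726 and 896. Replicate 1 had PER3 at 8.19 in DMSO and 6.78 in carfilzomib. For replicates 2 and 3 of both groups, these values argue against correct labels with an uneven response. Ribosomal RNA carry-over is excluded by the spread of PER3. Its largest SD on the log2 scale stayed at 1.30 without the library rich in RNA18SP4 (0.51 in the other sets). In the order DMSO, SHP1705, carfilzomib and combination, the crossings were runs of neighbours, with the last library followed by the first. Low PER3 with high HSPA1A was in DMSO replicates 2 and 3 and SHP1705 replicate 1. High PER3 with low HSPA1A was in SHP1705 2 and 3 and carfilzomib 1. Both were low in carfilzomib 2 and 3 and combination 1, and high in combination 2 and 3 and DMSO 1. A shift of labels along that order would give such runs, but the values cannot say how they arose. No library was given another label, and no biological explanation beyond the uneven response was tested.

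The stress genes of the MG132 set were high in the combination and not with MG132 alone, and RNA from other cells, a dose without effect and a joint effect of both drugs were weighed. RNA from other cells, of the composition found in the 4 other libraries with POSTN, is excluded as the source. This was read over 139 stress genes that rose in the combination. In those 4 libraries POSTN stood at 18.8% to 115% of the combination mean. Their stress gene excess over DMSO had medians of -0.778% to 1.02% of the combination excess. The highest upper quartile was 0.146 of the POSTN share, where 0.5 was the bound. RNA of another composition in the combination alone, such as from other cells stressed there, would pass this test unseen and stays open. With MG132 alone the heat shock list had a median log2 fold change of 0.00, so the MG132 libraries may have had no effective dose, a state that a dose under the response threshold gives as well. With carfilzomib at 24 h the median interaction of the proteasome subunits was 0.06 and those of HSPA8 (-0.60), UBB (-0.55) and DNAJA1 (-0.37) were negative, which leaves a joint effect open for MG132 at 8 h. An exchange of drug between groups is not what the levels show, since 0 of the libraries with PER3 above its gap had HSPA1A above its gap, and a dose that differed between the groups stays open.

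POSTN and CDKN2A were present in 7 libraries of the MG132 set, with 1075 and 1134 POSTN counts in SHP1705 replicates 2 and 3, 1337 and 6972 in MG132 replicates 1 and 3 and 2876, 6865 and 8040 in the combination, and 11 or fewer in the other 5. CDKN2A is deleted in MDA-MB-231 cells and had 23 to 252 counts in those 7 and 4 or fewer elsewhere. For 19 genes picked in MG132 replicate 3, the largest spread of the ratio to that library (interquartile range over median) was 0.565. Under 0.5 was set to speak for 1 source of RNA from other cells and 1 or more against it, after the value was seen. So 1 source could not be told from several, and an earlier bound of 1 would have counted 1 source as met. The spread was 0.227 to 0.245 in the combination libraries and 0.327 in SHP1705 replicate 3. It passed 0.5 in SHP1705 replicate 2 (0.565) and MG132 replicate 1 (0.562), which had 29 and 23 CDKN2A counts against 90 to 252 in the combination. What low counts add to the spread was not tested. The spread does not bear on whether other cells contributed at all, to which the counts of the deleted CDKN2A point. A drug effect in the cells is excluded by POSTN differing 1080-fold between the libraries labelled MG132. Carry-over from the combination is excluded by POSTN in MG132 replicate 3 at 115% of the combination mean, where its heat shock excess was 0.921% (quartiles 0.826% and 1.44% over 10 genes), and the stress gene excess of the other 3 libraries had medians of -0.778% to 0.112% beside POSTN at 18.8% to 22.4%.

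Other splits of the libraries of each contrast were run through the same fit and counted. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. In the MG132 set the real counts and the highest of the other splits were 1249 and 0 for SHP1705, 0 and 0 for MG132 (10 of 10 splits reached the real count), 9763 and 0 for the combination and 9487 and 0 for the combination against MG132, with 1 of 10 splits, the real one, for all but MG132. At 24 h they were 722 and 1 for SHP1705, 3472 and 0 for carfilzomib, 4424 and 0 for the combination and 1460 and 0 against carfilzomib. For the interactions, the real count was reached by 1 of 100 splits in the MG132 set (8108, highest other 7081) and at 24 h (78, highest other 14). The interaction splits shuffled all 12 libraries of a set over its 4 groups, so the single drug effects were broken up as well. They ask whether any treatment matters, and cannot tell an interaction from additive effects.

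In the carfilzomib set at 8 h, the labels gave 0 genes for SHP1705 where another split of the same libraries gave 3436, and 0 against 4926 for the interaction, so the libraries hold a structure that these labels do not follow. The other counts there were 3587 and 0 for the labels of carfilzomib, 0 and 0 for those of both drugs and 0 and 56 for those of both against carfilzomib, and the counts of 0 were reached by 10 of 10 splits or 100 of 100. Between sets, the real count was reached by 1 of 30 splits for the carfilzomib effect at 24 h minus 8 h (6965, highest other 5550), the effect of both drugs (3542, highest other 853) and carfilzomib minus MG132 (5187, highest other 5). The between-set splits exchanged treated and DMSO libraries within each set. They break up the effect in each set as well, so they cannot test the difference on its own. For the SHP1705 effect at 24 h minus 8 h, 6 of 30 splits reached 512 and the highest gave 4086, several times the real count, which points to a structure of the samples. For its difference between the 8 h sets the real count was 0 and the highest other 3859 (30 of 30 splits reach 0). A count of 0 is reached by every split by construction, so those tallies decide nothing.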

How the results depend on the processing

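The fits without 4 libraries of the MG132 set (those outside the combination with over 100 POSTN counts) and without 2 libraries of the carfilzomib set at 8 h (labelled SHP1705 replicate 1 and both drugs replicate 1) were chosen after the values were seen. Of 187 named gene results, 1 turned its sign with a call, POSTN in the interaction of the MG132 set, at 9.44 without the 4 libraries, where both single drugs have 1 library each. Other settings called POSTN there with a negative term, at -5.44 without the filter, -5.49 by DESeq2 and -6.00 without MG132 replicate 2. No gene called in the main fit of a contrast was called in the opposite direction. Relative log expression factors kept every count within 1.5 times. The combination results of the MG132 set, carfilzomib and both drugs at 24 h and the carfilzomib difference of 24 h minus 8 h stayed within 1.5 times of their counts under all settings run (the lowest were 7800 of 9487, 5982 of 8108 and 2493 of 3472, for the combination against MG132, the interaction of the MG132 set and carfilzomib at 24 h). For the counts that moved, the cause was not tested, except that left-out libraries and fits of fewer groups test with fewer samples. Libraries held 17800000 to 39300000 counts, and what depth limits was not tested on its own.

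For the MG132 set, SHP1705 gave 150 genes without the 4 libraries, a fit that leaves SHP1705 and MG132 with 1 library each, assumed to vary like the other groups. MG132 gave 303 without the filter, 3 with the replicate number as a block, 95 by DESeq2 and 22 in the fit of its groups alone. At 24 h, the fit of the groups alone gave 1171 for SHP1705 and 913 for the combination against carfilzomib, and the interaction gave 364 without the filter and 360 by DESeq2. For the labels at 8 h, SHP1705 gave 1050 without the filter and 5711 without the 2 libraries, and carfilzomib gave 0 with the block, 6719 with its groups alone and 7452 without the 2 libraries. Both drugs against DMSO gave 688 without the filter, 1 by DESeq2 and 2 with the groups alone, and against carfilzomib 502, 1 by DESeq2 and 4284 without the 2 libraries. The interaction there gave 2337 without the filter, 315 by DESeq2 and 7507 without the 2 libraries. The SHP1705 difference of 24 h minus 8 h gave 1675 without the filter, 83 with the block, 1252 by DESeq2, 4 with the groups alone and 5638 without the 2 libraries, and that between the 8 h sets 1309, 368 by DESeq2, 1 with the groups alone and 5505.

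Leaving out 1 library at a time gave 619 to 892 genes for SHP1705 in the MG132 set, 0 to 67 for MG132, 9163 to 9316 and 8829 to 9274 for the combination against DMSO and MG132, and 7667 to 7949 for the interaction. At 24 h the ranges were 419 to 687 for SHP1705, 2493 to 3756 for carfilzomib, 3453 to 3677 and 869 to 1852 for the combination against DMSO and carfilzomib, and 20 to 477 for the interaction. For the labels at 8 h they were 0 to 3662 for SHP1705, 0 to 3115 for carfilzomib, 0 to 0 and 0 to 2 for both drugs against DMSO and carfilzomib, and 0 to 5093 for the interaction. For 24 h minus 8 h they were 5813 to 7176 for carfilzomib, 2126 to 4225 for both drugs and 76 to 4825 for SHP1705, and between the 8 h sets 3354 to 5679 for the inhibitors and 0 to 4629 for SHP1705.

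Of 222 list calls by camera in 580 tests, 57 were kept with an estimated correlation, while fry called 235 in its directional form (154 of the 222) and 350 in its mixed form (164 of the 222). Over genes with a mean of at least 5 CPM, the correlation of SHP1705 alone and on top of the inhibitor was -0.01 in the MG132 set, -0.81 for the labels at 8 h and 0.50 at 24 h, that of SHP1705 in the MG132 set with 24 h 0.41 and that of the labels at 8 h with 24 h -0.03. Deviations from the group means were correlated between libraries with the same replicate number. They gave -0.11 to 0.18 in the MG132 set, -0.75 to 0.33 in the carfilzomib set at 8 h and -0.05 to 0.05 at 24 h. In that order, 3, 0 and 5 of 12 libraries were closest to their own number, so no pairing by number was seen. At 8 h the labelled groups mix libraries with different readouts, so the values there cannot test a pairing.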

Other observations

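Genes of a secreted protease and of xenobiotic metabolism changed in the MG132 set and at 24 h. PLAU, the urokinase gene, averaged 340 ± 5.1 CPM (SD, n = 3) after SHP1705 for 8 h and 75.6 ± 3.08 in the combination of the MG132 set, while at 24 h it averaged 287 ± 5.8 after SHP1705 and 301.5 ± 6.6 in the combination. CYP1B1 rose from 195 ± 12.4 to 359 ± 9.24 after SHP1705 for 8 h. Among 8 measured metallothioneins, which bind zinc and copper, 4 fell and 1 rose in the combination of the MG132 set (5 and 1 adjusted over the list alone), with a median log2 fold change of -0.53, and camera did not call the list (adjusted p = 0.062). Of 14 replication-dependent histone genes, 6 fell there (6 adjusted over the list alone), and camera's call was lost (adjusted p = 0.095 with an estimated correlation).

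In the carfilzomib set at 8 h, liver transcripts chosen after their values were seen stood out in 2 libraries. The library labelled SHP1705 replicate 1 held 4.06 CPM of ALB, the albumin gene, 1.38 of APOB and 1.91 of TF, and that labelled with both drugs replicate 3 held 3.65, 1.37 and 2.31. All 3 genes were lower in the other 10 libraries. The ribosomal RNA gene RNR1 was at 4920 CPM in the library labelled SHP1705 replicate 1.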
